A study of Mus musculus with 12 samples.

How the data were processed

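BV2 cells, an immortalised mouse microglial line, were profiled on 12 Affymetrix gene-level arrays, 3 for each of 4 treatments. Per the labels' protocols, the cells received 1.5% DMSO vehicle for 3 h, LPS for 1 h after 2 h of vehicle, telmisartan alone, or telmisartan for 2 h followed by LPS for 1 h. LPS (lipopolysaccharide) is a bacterial cell wall component that activates Toll-like receptor 4, and telmisartan is a blocker of the angiotensin II type 1 receptor that also activates PPAR gamma in part. The dose of telmisartan is not given in the sources used here. The labels describe the samples of a group as independent. The titles carry only running numbers, so nothing beyond that wording ties an array to a separate culture, and p-values measure the spread between these arrays.

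The deposited values are log2 RMA signals that the authors made in Affymetrix Expression Console (engine 1.4.1.46), per the file headers. The same headers record background correction, quantile normalization over the 12 arrays together, perfect-match probes and summarisation by median polish. A labelling protocol names an earlier array design of the same family, whereas the file headers name the second-generation mouse gene array, whose features are used here. The values came in a summary table with 2 decimals and in a series matrix with 5 decimals, and the pair differed by at most 0.005, so scale and centring were the same in both. The summary table was used for the results and the series matrix as an alternative. Both tables held 0 columns of other samples.

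Array medians over all features lay between 4.08 and 4.13, and correlations between arrays over genes ran from 0.995 to 0.9974. An array has no read depth, and precision is limited by the number of arrays. The median residual SD of a gene was 0.117 on the log2 scale.

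Of 41345 features, 23521 were listed with 1 gene symbol, 1820 with several entries and 16004 with none in the platform annotation used here. Of the features with 1 symbol, 23328 were matched to the reference gene table through their Entrez identifiers to update symbols, and 193 kept the symbol of the platform annotation. Each gene was represented by its feature with the highest mean signal over all arrays, which left 22180 genes, 1082 of them with more than 1 feature. Features with several symbol entries or none were tested apart from the genes. Members of the fixed gene lists without a feature of their own were not analysed here.

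All 12 arrays entered a single linear model with 4 group means in limma 3.58.1 (R 4.3.3, statmod 1.5.0), with 8 residual degrees of freedom and 4.99 prior degrees of freedom from eBayes. Contrasts were LPS minus DMSO, telmisartan minus DMSO, telmisartan+LPS minus LPS, telmisartan+LPS minus telmisartan, the interaction (the difference between the LPS effects with and without the drug), and the average telmisartan effect over both LPS states. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. For the lists, limma's camera was run with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and fry on the same fit, each adjusted over 40 lists within a comparison. The lists, the contrasts, the naming rule and the alternatives listed at the end were fixed before the data were examined. Two-sided exact permutation of the drug labels within each LPS state, which has 200 distinct splits and a smallest p of 0.005, was added after the results were seen, as were an average LPS effect over both drug states and a set of tests on histone and small nucleolar RNA genes.

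Genes were named by rule. The rule took, in each comparison, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap (for the interaction and the average effect, called genes only), leaving predicted gene models and families of small or many-copy RNAs or receptors out of the naming but not out of the counts. It also took up to 4 members of each fixed list with the largest absolute change, called or not, and Tnf, Il1b, Il6, Nos2, Ptgs2, Tlr4, Cd14 and the genes of the angiotensin and PPAR receptors in every comparison. A gene named outside this rule is marked where it appears.

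The comparisons of LPS-changed genes share the LPS arrays with the drug comparison, so groups without a drug effect were simulated 100 times against the same arrays. The fit was also tested on simulated data for 22180 genes with 50 genes changed at each of several sizes. At 1.5-fold, the fit recovered 41 of 50 genes for LPS minus DMSO, 40 for telmisartan minus DMSO, 32 for telmisartan+LPS minus LPS, 37 for telmisartan+LPS minus telmisartan, 23 for the interaction and 45 for the average telmisartan effect. At 1.3-fold it recovered 25, 14, 19, 30, 2 and 33 in the same order. Changes of up to 4-fold were put in together, and many called genes loosen the adjusted threshold. Recovery may therefore be lower where few genes are called, as in the drug comparisons.

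Alternatives were a repeated quantile normalization, centring of each array on its median, the series matrix values, a filter that kept 12784 genes above the array median on at least 3 arrays, every feature in place of 1 per gene, eBayes with trend and robust options, array weights, a fit on the groups of a comparison alone, a term for sets of 4 consecutive running numbers, a 1.5-fold minimum, and leaving out each array in turn. The closing section gives their effect.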

Results

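Gene expression was measured in BV2 mouse microglial cells after vehicle (DMSO), LPS for 1 h, telmisartan, or telmisartan for 2 h followed by LPS for 1 h, with 3 arrays in each of the 4 groups. The series asked how telmisartan and LPS act on these cells singly and together. Values are log2 RMA signals, differences are log2 changes with the standard error of the limma fit, and group means carry the SD of 3 arrays. The first principal component held 20.3% of the variance and separated the arrays with LPS from those without. Replicates 1 and 3 of the telmisartan+LPS group stood apart from the other arrays, replicate 1 at -17.31 on the third component and replicate 3 at -20.18 on the second.

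The first comparison asked what 1 h of LPS does without the drug. Cytokine and chemokine transcripts had the largest rises. The neutrophil chemokine Cxcl2 rose by 4.23 (SE 0.23), an 18.7-fold change, Il1b, which encodes the pyrogenic cytokine interleukin-1 beta, by 4.19 (SE 0.24), Il6 by 3.75 (SE 0.24), the interferon-inducible chemokine Cxcl10 by 3.73 (SE 0.10) and Il1a by 3.09 (SE 0.19). Il6 went from 4.73 ± 0.16 (SD, n = 3) in DMSO to 8.48 ± 0.098 (SD, n = 3) in LPS, and Tnf, already bright at 10.84 ± 0.19 (SD, n = 3), reached 12.43 ± 0.059 (SD, n = 3). In limma with Benjamini-Hochberg adjustment the adjusted p was 6.55e-07 for Cxcl2, 8.15e-07 for Il1b, 1.41e-06 for Il6, 4.05e-10 for Cxcl10 and 8.21e-07 for Tnf.

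Negative regulators of the response rose in the same hour. Tnfaip3, the ubiquitin-editing inhibitor of NF-kB, rose by 2.68 (SE 0.08), Zfp36, which destabilises cytokine mRNAs, by 1.51 (SE 0.09), and Socs3, an inhibitor of cytokine receptor signalling, by 1.49 (SE 0.09), where a second, dim feature of Socs3 was at 0.08. Of 26 measured NF-kB target and early Toll-like receptor response genes, 15 rose over all genes tested and 20 rose adjusted over the list alone, with 1 lower by that count. They included the nuclear NF-kB cofactor Nfkbiz at 1.39 and the stress gene Ier3 at 1.29. Among 24 MAPK and cytokine feedback inhibitors 5 rose, and 8 rose and 1 fell adjusted over the list alone, with the MAPK phosphatase Dusp1 at 0.88. Limma's camera gave a Benjamini-Hochberg adjusted p of 4.57e-44 for the NF-kB list (adjusted p = 0.000183 with an estimated correlation) and 1.22e-12 for the feedback list (adjusted p = 0.021 with an estimated correlation).

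Of 22 cytokine genes 9 rose, and 11 adjusted over the list alone, and of 17 chemokine genes 6 rose, and 7 adjusted over the list alone, with Ccl4 at 0.85 and Ccl5 at 0.75. Immediate early transcription factors, the first genes switched on by many stimuli, had 6 rises among 25 and 8 adjusted over the list alone, led by Btg2 at 1.10, Myc at 0.82 and Egr2 at 0.71. Of 14 inflammatory enzymes and NADPH oxidase genes 3 rose, and 4 adjusted over the list alone. These were Acod1, which makes itaconate, at 1.28, the prostaglandin-producing cyclooxygenase Ptgs2 at 1.24 and the oxidase subunit Cybb at 0.47, while the nitric oxide synthase gene Nos2 was at 0.42 and missed the threshold (limma with Benjamini-Hochberg adjustment, adjusted p = 0.12). With trend and robust options Nos2 passed it (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0244). In limma's camera the adjusted p was 5.91e-18 for cytokines, 2.26e-14 for chemokines, 2.21e-12 for immediate early factors and 6.85e-07 for inflammatory enzymes, and with an estimated correlation 0.000898, 0.000898, 0.0173 and 0.00476 in that order.

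Other lists were carried by few members. In the inflammasome list only Nlrp3, the sensor subunit, at 1.26 and Il1b rose among 13 genes over all genes tested and adjusted over the list alone, and the list median was -0.00333 against a mean of 0.439 (camera in limma, adjusted p = 0.0105, and adjusted p = 0.161 with an estimated correlation). Of 17 p53 targets 3 rose, and 6 adjusted over the list alone, among them the death receptor gene Fas at 1.04, Plk2 at 0.47 and Btg2, which is in the immediate early list too (camera in limma, adjusted p = 1.3e-05, and adjusted p = 0.0207 with an estimated correlation). Of 16 antigen presentation genes 1 rose, and 3 adjusted over the list alone, with the checkpoint ligand Cd274 at 0.90 (camera in limma, adjusted p = 0.0131, and adjusted p = 0.0677 with an estimated correlation). Among 21 LPS and Toll-like receptor sensing genes, the receptor gene Tlr2 at 0.53 and the kinase gene Irak2 at 0.37 rose over all genes tested and adjusted over the list alone (camera in limma, adjusted p = 0.0173, and adjusted p = 0.102 with an estimated correlation). The LPS receptor gene Tlr4 was at 0.09 and its co-receptor gene Cd14 at 0.08, neither past the threshold and both dependent on single arrays, with Tlr4 at -0.0067 without LPS replicate 1 and Cd14 at 0.045 without DMSO replicate 1. The sensing list missed the camera threshold without DMSO replicate 1 (limma, adjusted p = 0.0545) and without LPS replicate 2 (adjusted p = 0.0765).

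A pair of lists shifted down. Of 26 oxidative phosphorylation genes 25 were lower, with a mean of -0.118 (camera in limma, adjusted p = 4.35e-06, and adjusted p = 0.216 with an estimated correlation), and of 19 G2 and M phase genes 17 were lower, with a mean of -0.0596 (camera in limma, adjusted p = 0.0479, and adjusted p = 0.335 with an estimated correlation). When 1 array was left out, the G2 and M phase call was kept only without DMSO replicate 2, LPS replicate 3, telmisartan replicate 3 or telmisartan+LPS replicate 1, and the adjusted p of camera in limma reached 0.224 without LPS replicate 2. No member of either list was past the threshold singly, with 0 over all genes tested and 0 adjusted over the list alone. In total 84 genes rose and 11 fell of 22180, against 2001 genes at an unadjusted p under 0.05, and 6 of the rises were at least 4-fold. The number of falls was 3, 4 and 2 without DMSO replicates 1, 2 and 3, 3 without LPS replicate 2, 24 without LPS replicate 3 (15 of them small nucleolar RNA genes) and 19 without telmisartan+LPS replicate 1. It was 26 with dim genes left out and 23 with trend and robust options. Falls were small, with the dim zinc finger gene Zfp273 at -0.89 (SE 0.13), the growth arrest gene Gadd45g at -0.63, the mitochondrial DNA polymerase subunit Polg2 at -0.58 and Arrdc2 at -0.44. Groups did not overlap in 15.7% of genes, where chance gives 10%. Of the genes named for this comparison, Ccl5, Egr2, Irak2, Cybb, Plk2, Gadd45g, Polg2 and Arrdc2 each missed the threshold under at least 1 alternative setting.

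The second comparison asked what telmisartan does without LPS. The MAPK phosphatase gene Dusp5 was at -0.41 (SE 0.07), the TNF receptor adaptor gene Traf1 at -0.44 (SE 0.10), Ier3 at -0.41 (SE 0.10) and the cholesterol exporter gene Abca1 at -0.25 (SE 0.07). None passed the threshold in limma with Benjamini-Hochberg adjustment, where the adjusted p was 0.547 for Dusp5, 0.801 for Traf1 and 0.86 for Ier3 and Abca1. Of the drug's receptor genes, Agtr1a was at -0.05, Agtr1b at -0.01 and Pparg at 0.03, none past the threshold and each with either sign when single arrays were left out. Limma called 0 genes at an adjusted p under 0.05 and 1222 at an unadjusted p under 0.05, and the smallest adjusted p was 0.54. Groups did not overlap in 11.4% of genes, where chance gives 10%.

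Small shifts of whole lists passed camera with its preset correlation. Genes of cholesterol synthesis and other SREBP2 targets were higher in 13 of 18, with a mean of 0.078 (camera in limma, adjusted p = 0.00147, and adjusted p = 0.684 with an estimated correlation). Examples are the sterol synthesis enzymes Msmo1 at 0.22, Cyp51 at 0.22 and Hmgcs1 at 0.21. Ribosomal protein genes were lower in 21 of 22, with a mean of -0.107 (camera in limma, adjusted p = 0.00147, and adjusted p = 0.684 with an estimated correlation), and oxidative phosphorylation genes in 22 of 26, with a mean of -0.0596 (camera in limma, adjusted p = 0.0412, and adjusted p = 0.727 with an estimated correlation). Each of the 3 lists had 0 members past the threshold over all genes tested and 0 adjusted over the list alone. With an estimated correlation 0 of 40 lists passed. The directional test of fry gave 0 too, while its mixed test, which counts members moving either way, gave 7. When 1 array was left out, the oxidative phosphorylation call was lost without any DMSO replicate or telmisartan replicate 2 or 3 (camera in limma, adjusted p up to 0.29), and the ribosomal call without DMSO replicate 2 (adjusted p = 0.0763).

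The third comparison asked what telmisartan changes in cells given LPS. No gene passed the threshold singly. Il6 was at 7.13 ± 0.68 (SD, n = 3) with telmisartan and LPS against 8.48 ± 0.098 (SD, n = 3) with LPS alone, a difference of -1.35 (SE 0.24). Il1b was at -1.08 (SE 0.24), Il1a at -0.73 (SE 0.19, and at -0.45 without telmisartan+LPS replicate 3), Ptgs2 at -0.65 (SE 0.13), the myeloid growth factor gene Csf2 at -0.59 (SE 0.14), Fas at -0.59 (SE 0.10) and Nlrp3 at -0.56 (SE 0.08). Tnf differed by -0.19 (SE 0.09). Within telmisartan+LPS, replicate 3 was lowest, with Il6 at 6.36 against 7.63 and 7.41, and Il1b at 8.54 against 9.66 and 9.28. The SE pools the spread of all 4 groups, so it does not show the wider spread of this group. In limma with Benjamini-Hochberg adjustment the adjusted p was 0.18 for Il6, 0.263 for Il1b and Ptgs2, 0.134 for Fas and Nlrp3 and 0.522 for Tnf.

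**Figure D1:**
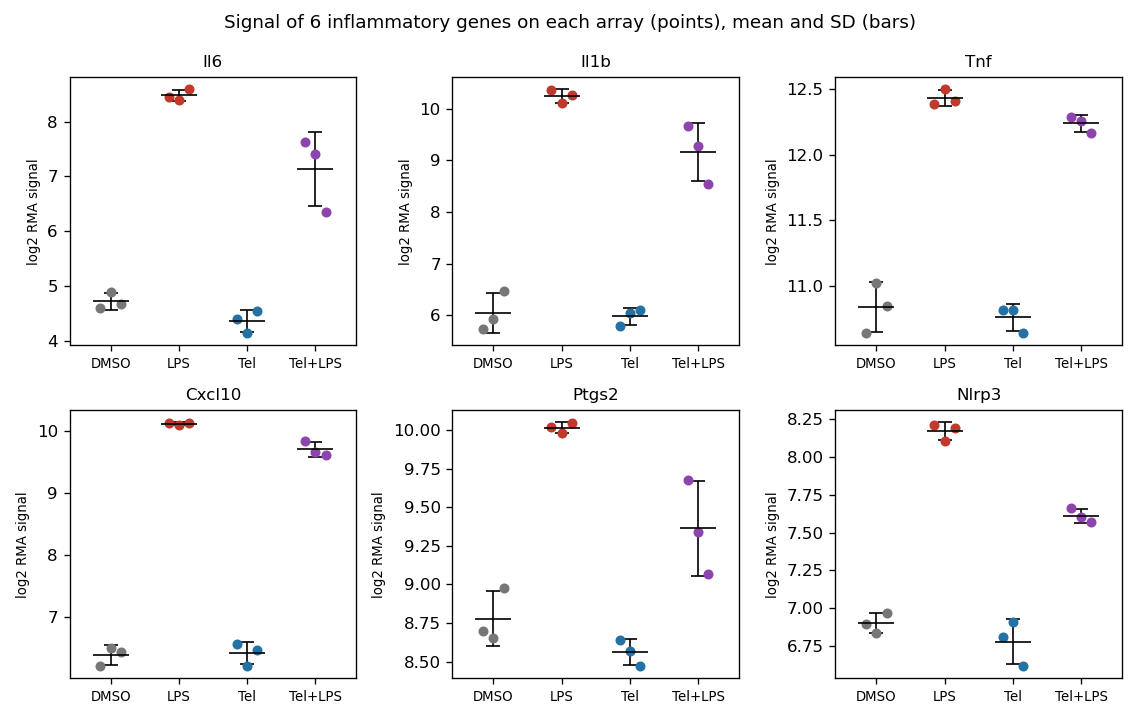
Log2 RMA signal of Il6, Il1b, Tnf, Cxcl10, Ptgs2 and Nlrp3 on each of the 12 arrays by treatment group; points are arrays, and bars are the group mean and SD (n = 3). With LPS, the Il6 mean was 8.48 without the drug and 7.13 with it, while Tnf was 12.43 and 12.24.

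The NF-kB list fell as a group. Of its 26 members 23 were lower with the drug, the mean was -0.192, and 14 fell adjusted over the list alone with 1 rise, against 0 over all genes tested. Tnfaip3 was at -0.44, Ier3 at -0.43, Nfkbiz at -0.42 and Traf1 at -0.41. Camera in limma gave an adjusted p of 3.46e-12 (adjusted p = 0.0181 with an estimated correlation), and fry gave 0.00142. Cytokines fell too, lower in 19 of 22 with a mean of -0.253 and 7 falls adjusted over the list alone against 0 over all genes tested (camera in limma, adjusted p = 5.77e-06, and adjusted p = 0.0402 with an estimated correlation). Chemokines were lower in 13 of 17 with a mean of -0.178, 2 falls adjusted over the list alone and 0 over all genes tested, with Cxcl2 at -0.64 and Cxcl10 at -0.41 (camera in limma, adjusted p = 0.000194, and adjusted p = 0.05 with an estimated correlation, just under the threshold before rounding). An exact test on array means, not fixed beforehand, gave p = 0.1 for each of these lists. That is the smallest p that 3 against 3 arrays allow, so chance in how the arrays fell into groups stays open.

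**Figure D2:**
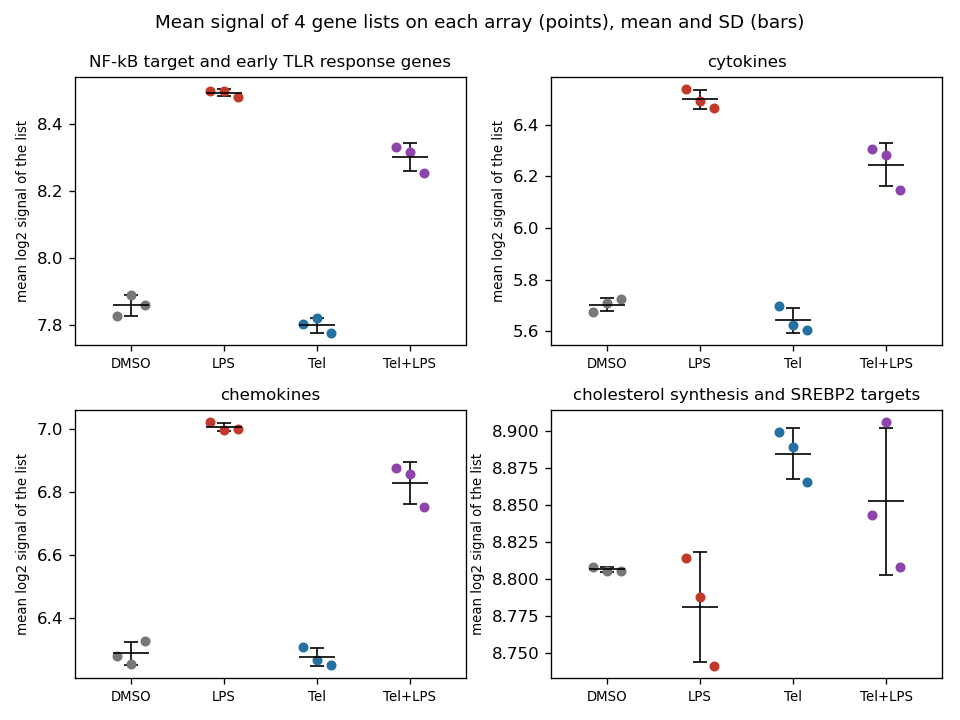
Mean log2 RMA signal of the NF-kB and early response, cytokine, chemokine and cholesterol synthesis lists on each of the 12 arrays by treatment group; points are arrays, and bars are the group mean and SD (n = 3). The difference between the groups with LPS, drug minus vehicle, is -0.192 for the NF-kB list, -0.253 for cytokines and -0.178 for chemokines.

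Further lists passed camera only with the preset correlation. Lower lists were immediate early factors (mean -0.111, 2 falls adjusted over the list alone, adjusted p = 0.000545, and adjusted p = 0.253 with an estimated correlation), with the zinc finger factor gene Egr2 at -0.42, and feedback inhibitors (mean -0.101, 4 falls adjusted over the list alone, adjusted p = 0.00017, and adjusted p = 0.253 with an estimated correlation) in limma's camera. The inflammasome list had a mean of -0.167 and 3 falls adjusted over the list alone (camera in limma, adjusted p = 0.00548, and adjusted p = 0.219 with an estimated correlation). Its members include Nlrp3 at -0.56 and Il1b at -1.08, and Il1b is in the cytokine list too. Limma's camera gave p53 targets a mean of -0.071 with 3 falls and 1 rise adjusted over the list alone (adjusted p = 0.0384, and adjusted p = 0.254 with an estimated correlation). Toll-like receptor sensing genes had a mean of -0.0725 (camera in limma, adjusted p = 0.0149, and adjusted p = 0.183 with an estimated correlation), and hypoxia targets a mean of -0.0631 (camera in limma, adjusted p = 0.0297, and adjusted p = 0.254 with an estimated correlation). Each of these lists had 0 members past the threshold over all genes tested, and the last pair had 0 adjusted over the list alone. Inflammatory enzyme and NADPH oxidase genes, lower in 8 of 14 and higher in 6, and interferon response genes, higher in 16 of 27, missed the camera threshold (limma, adjusted p = 0.122 and adjusted p = 0.433).

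Several of these calls were lost when 1 array was left out. Without telmisartan+LPS replicate 3 the mean was -0.0404 for p53 targets (camera in limma, adjusted p = 0.235), -0.0406 for hypoxia targets (adjusted p = 0.22), -0.0492 for sensing genes (adjusted p = 0.19) and -0.12 for the inflammasome list (adjusted p = 0.0637). The p53 call was also lost without LPS replicate 1 or 2 or telmisartan+LPS replicate 2, the hypoxia call without LPS replicate 2 or telmisartan+LPS replicate 2, and the sensing call without LPS replicate 2 (camera in limma, adjusted p up to 0.154). Feedback inhibitors were at -0.0663 without LPS replicate 2 and kept their call.

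Oxidative phosphorylation genes were higher in 23 of 26 with a mean of 0.0826 (camera in limma, adjusted p = 0.00695, and adjusted p = 0.527 with an estimated correlation), ribosomal protein genes in 17 of 22 with a mean of 0.0867 (camera in limma, adjusted p = 0.0384, and adjusted p = 0.527 with an estimated correlation), and cholesterol synthesis genes in 14 of 18 with a mean of 0.0711 (camera in limma, adjusted p = 0.0384, and adjusted p = 0.482 with an estimated correlation). All 3 had 0 members past the threshold over all genes tested and 0 adjusted over the list alone. The ribosomal mean was 0.144 without telmisartan+LPS replicate 1 and 0.0538 without replicate 3 of that group. Its call was lost without LPS replicate 2 or 3 or telmisartan+LPS replicate 2 or 3 (camera in limma, adjusted p up to 0.311). The cholesterol synthesis mean was 0.0444 without telmisartan+LPS replicate 2. Its call was lost without that array, telmisartan+LPS replicate 1 or LPS replicate 2 or 3 (camera in limma, adjusted p up to 0.342). The oxidative phosphorylation call was lost without LPS replicate 2 or telmisartan+LPS replicate 2 (camera in limma, adjusted p up to 0.215). Abca1 was at -0.41 (SE 0.07, limma with Benjamini-Hochberg adjustment, adjusted p = 0.134), and the stress-induced gene Sesn2 was at 0.46 (SE 0.11).

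Limma called 0 genes in this comparison at an adjusted p under 0.05, against 2176 at an unadjusted p under 0.05, 1221 of them higher and 955 lower, and groups did not overlap in 13% of genes, where chance gives 10%. With trend and robust options the count was 14, 6 higher and 8 lower, among them Tnfaip3, Nfkbiz, Nlrp3, Abca1 and Csf1. Without LPS replicate 3 it was 5, all of them small nucleolar RNA genes and higher with the drug, without DMSO replicate 3 it was 1, lower, and without telmisartan replicate 1 it was 1, higher. When the genes called in LPS minus DMSO were taken out of every list, an alternative chosen after seeing the data, 1 list passed camera, and the NF-kB list missed the threshold (limma, adjusted p = 0.156).

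The fourth comparison asked what LPS does in cells that had the drug first. The leading genes were those named for LPS alone. Cxcl2 rose by 3.92 (SE 0.23), Cxcl10 by 3.28 (SE 0.10), Il1b by 3.17 (SE 0.24), Il6 by 2.77 (SE 0.24), Il1a by 2.31 (SE 0.19), Tnfaip3 by 2.10 (SE 0.08) and Tnf by 1.48 (SE 0.09). In limma with Benjamini-Hochberg adjustment the adjusted p was 2.24e-06 for Cxcl2, 2.07e-09 for Cxcl10, 1.27e-05 for Il1b and 5.2e-05 for Il6. Ptgs2 rose by 0.80 and Nlrp3 by 0.83. The mitochondrial transcription termination factor gene Mterf3 fell by 0.41 and Fam185a fell by 0.40, and the calls of these genes and of Ptgs2 were lost under several alternatives.

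Of 26 NF-kB list members all 26 were higher, 11 rose over all genes tested and 17 adjusted over the list alone (camera in limma, adjusted p = 2.29e-25, and adjusted p = 0.00143 with an estimated correlation). Cytokines had 6 rises among 22 and 11 adjusted over the list alone (camera in limma, adjusted p = 4.93e-11, and adjusted p = 0.00553 with an estimated correlation), chemokines 5 among 17 and 6 adjusted over the list alone (camera in limma, adjusted p = 4.72e-05, and adjusted p = 0.0282 with an estimated correlation), and inflammatory enzymes 2 among 14 and 4 adjusted over the list alone (camera in limma, adjusted p = 4.16e-05, and adjusted p = 0.0171 with an estimated correlation). Interferon response genes were higher in 20 of 27, with 3 rises over all genes tested and 6 adjusted over the list alone, and the transcription factor gene Irf1 was at 0.81 (camera in limma, adjusted p = 5.03e-05, and adjusted p = 0.0302 with an estimated correlation). In LPS minus DMSO the same list had 3 rises, 6 rises and 3 falls adjusted over the list alone, and missed the camera threshold (limma, adjusted p = 0.134), and its interaction test missed it too (camera in limma, adjusted p = 0.309).

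Homeostatic microglia markers were higher in 16 of 21, with a mean of 0.103, 0 over all genes tested and 1 adjusted over the list alone (camera in limma, adjusted p = 0.0155, and adjusted p = 0.109 with an estimated correlation), and G2 and M phase genes were lower in 16 of 19, with a mean of -0.0853 (camera in limma, adjusted p = 0.000842, and adjusted p = 0.109 with an estimated correlation). Camera passed 10 higher lists and 1 lower list of 40, and 5 with an estimated correlation. Altogether 55 genes rose and 3 fell, against 3024 at an unadjusted p under 0.05, and 48 of the 58 were called in LPS minus DMSO, all 48 higher in both, where independent lists would share 0.25. Groups did not overlap in 17% of genes, where chance gives 10%. Without telmisartan replicate 3 the count was 31, and it was 35 both with a 1.5-fold minimum and with only these groups in the fit. With trend and robust options 104 rose and 60 fell, with dim genes left out 90 and 36, and with every feature 49 and 14. The number of falls was 0 without telmisartan replicate 3, 1 without telmisartan replicate 1 or 2 or telmisartan+LPS replicate 3, 5 without LPS replicate 2 or 3 and 7 without telmisartan+LPS replicate 1.

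Whether the LPS effect differed with the drug was tested by the interaction. Of single genes, Il1b was at -1.02 (SE 0.34), Il6 at -0.98 (SE 0.34, and at -0.59 without telmisartan+LPS replicate 3), Fas at -0.62 (SE 0.14), Tnfaip3 at -0.58 (SE 0.11), Nlrp3 at -0.43 (SE 0.11) and the interferon-induced gene Ifit3 at 0.89 (SE 0.17). In limma with Benjamini-Hochberg adjustment the adjusted p was 0.417 for Tnfaip3 and Ifit3 and 0.604 for Il1b, Il6 and Nlrp3. As lists, NF-kB targets had a mean interaction of -0.133 (camera in limma, adjusted p = 0.000539, and adjusted p = 0.316 with an estimated correlation), cytokines -0.192 (adjusted p = 0.0269, and adjusted p = 0.354 with an estimated correlation) and chemokines -0.167 (adjusted p = 0.0125, and adjusted p = 0.316 with an estimated correlation). The cytokine call was lost without DMSO replicate 1, LPS replicate 1 or telmisartan replicate 1 (camera in limma, adjusted p up to 0.125), and the chemokine call without telmisartan+LPS replicate 3 (adjusted p = 0.116). Camera passed 6 of 40 lists, with an estimated correlation 0, and the directional test of fry 0, while its mixed test passed 11. Limma called 0 genes at an adjusted p under 0.05, against 1725 at an unadjusted p under 0.05. With trend and robust options the count was 1, and without LPS replicate 3 it was 3, all of them small nucleolar RNA genes.

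A set of 119 genes higher in the average LPS effect was chosen after seeing the data, by an estimate independent of the interaction. Of these, 91 had a smaller and 27 a larger LPS effect with the drug, with 1 equal, and the median interaction was -0.157 (two-sided exact permutation of drug labels, p = 0.115). The LPS effect with the drug, as a share of that with vehicle on the log2 scale, had a median of 78.2% over the genes. Adjusted over these genes alone, 3 passed the interaction test in limma with Benjamini-Hochberg adjustment, Tnfaip3 (adjusted p = 0.0191), Fas (adjusted p = 0.0308) and Mir221 (adjusted p = 0.0487), the last a microRNA gene named after its values were seen. Across these genes, which are not independent replicates, the LPS effects with and without the drug had a Pearson r of 0.958, a Spearman rho of 0.736 and a total least squares slope of 0.807. Over all 22180 genes r was 0.34, rho 0.176 and the slope 1.11.

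**Figure D3:**
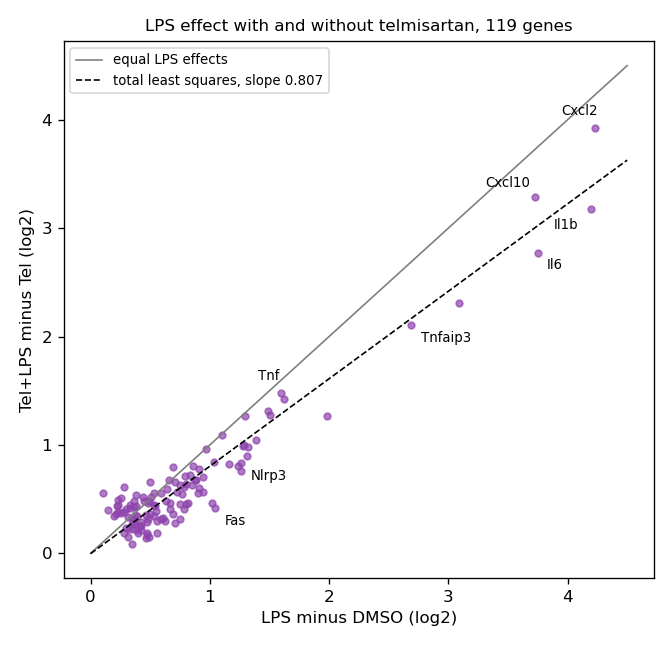
LPS effect with telmisartan (y axis, log2) against LPS effect with vehicle (x axis, log2) for the 119 genes higher in the average LPS effect; each point is a gene, the solid line marks equal effects and the dashed line is the total least squares fit. The fitted slope is 0.807, and Tnfaip3 and Fas, 2 of the 3 genes past the interaction test over these genes alone, are named on the plot.

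Of the 95 genes called in LPS minus DMSO, 0 were called in telmisartan+LPS minus LPS in either direction by limma at an adjusted p under 0.05. Of the 84 raised by LPS, 82 (97.6%) were lower with the drug, with a median of -0.252, and 48 were lower adjusted over these genes alone. Groups simulated without a drug effect against the same LPS arrays gave 55.4% on average, between 38.2% and 68.8%, a median of -0.0141 and 0 to 3 genes adjusted over the list alone. The simulation addresses the sharing of the LPS arrays and does not exclude chance in how the arrays fell into groups. The genes are not independent replicates, so the distance from these simulated ranges is not a measure of significance. For the median interaction of the 119 genes, the two-sided exact permutation of drug labels gave p = 0.115. In the 119 genes of the average LPS effect, 44 were lower adjusted over these genes alone. Across all genes, the drug effects with and without LPS had a Pearson r of -0.0249 and a Spearman rho of -0.0369.

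The last comparison set the 6 arrays with telmisartan against the 6 without, at equal LPS. The histone H4 gene H4c14 rose by 0.77 (SE 0.09, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0341), the 1 gene past the threshold, against 1624 at an unadjusted p under 0.05. Abca1 was at -0.33 (SE 0.05), Traf1 at -0.43 (SE 0.07), Ier3 at -0.42 (SE 0.07), Nlrp3 at -0.34 (SE 0.06) and Csf1, the macrophage growth factor gene, at -0.34 (SE 0.06). The adjusted p in limma was 0.0667 for Abca1, 0.105 for Traf1 and Nlrp3, and 0.119 for Csf1. When 1 array was left out, H4c14 kept its call only without telmisartan replicate 1 or 2, and it lost the call with every feature tested and with a term for sets of running numbers. With trend and robust options 12 genes were called, with Abca1, Traf1, Ier3, Nlrp3 and Csf1 among them.

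The NF-kB list fell, lower in 23 of 26 with a mean of -0.125 and 11 falls adjusted over the list alone against 0 over all genes tested (camera in limma, adjusted p = 6e-12, and adjusted p = 0.0193 with an estimated correlation). Cytokines fell with a mean of -0.157 and 4 falls adjusted over the list alone (camera in limma, adjusted p = 2.53e-06, and adjusted p = 0.0337 with an estimated correlation). Both averages rest more on the arrays with LPS. The drug difference was -0.192 with LPS and -0.059 without it for the NF-kB list, and -0.253 and -0.0611 for cytokines. Neither list passed camera in telmisartan minus DMSO. Cholesterol synthesis genes were higher in 15 of 18 with a mean of 0.0745 and 2 rises adjusted over the list alone, with Msmo1 at 0.17 and the sterol sensor partner gene Insig1 at 0.16 (camera in limma, adjusted p = 6.37e-05, and adjusted p = 0.197 with an estimated correlation). Integrated stress response genes, induced by amino acid shortage and related stresses, had a mean of 0.0586 and 3 rises adjusted over the list alone, with Sesn2 at 0.37 and the glutathione-degrading enzyme gene Chac1 at 0.35 (camera in limma, adjusted p = 0.012, and adjusted p = 0.197 with an estimated correlation). The last 3 lists had 0 members past the threshold over all genes tested. The stress response call was lost without DMSO replicate 1, LPS replicate 2 or telmisartan+LPS replicate 3 (camera in limma, adjusted p up to 0.0657). Camera passed 3 higher and 6 lower lists of 40, and 2 with an estimated correlation. In the two-sided exact permutation of drug labels the p was 0.005, the smallest the 200 splits can give, for the NF-kB list and for disease-associated microglia genes (mean -0.0396). It was 0.01 for cytokines, cholesterol synthesis and oligodendrocyte markers, and over 40 lists the Benjamini-Hochberg adjusted value was 0.08 for all 5.

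Lists chosen for the drug's known targets did not pass camera in any comparison. In the average effect the renin-angiotensin list had a mean of -0.00963 over 9 genes (camera in limma, adjusted p = 0.742) and PPAR target genes one of -0.0128 over 23 genes, with 0 over all genes tested and 1 fall adjusted over the list alone (camera in limma, adjusted p = 0.684). The mixed test of fry in limma passed the PPAR target list here (adjusted p = 1.71e-06), in telmisartan minus DMSO (adjusted p = 0.00158) and in telmisartan+LPS minus LPS (adjusted p = 1.55e-05). It also passed for LPS without the drug (limma, adjusted p = 6.64e-06). Such a pass is not particular to PPAR targets. Of 40 lists, the mixed test passed 15 in the average effect and 7 in telmisartan minus DMSO. It passed 20 in telmisartan+LPS minus LPS and 19 in LPS minus DMSO. Several receptor genes lay below the array median in every group, with Agtr1a at 3.23 ± 0.081 (SD, n = 3), Agtr2 at 3.00 ± 0.095 (SD, n = 3) and Pparg at 3.18 ± 0.14 (SD, n = 3) in DMSO.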

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

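The permutation of drug labels, the slope over other genes, the brightness-matched lists and the small RNA correlations were tests chosen only after the results were seen, whereas the counts over other splits of the arrays were fixed beforehand.

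The LPS effect differed with the drug for several gene lists by limma's camera with the preset correlation. The mean interaction was -0.133 for NF-kB targets, -0.192 for cytokines, -0.167 for chemokines and -0.16 for the inflammasome list (adjusted p = 0.0443). With an estimated correlation the adjusted p of limma's camera was 0.316, 0.354, 0.316 and 0.354 in that order, and with the preset one the inflammasome call was kept in 5 of 12 leave-one-out fits, with an adjusted p of 0.21 without telmisartan+LPS replicate 3. Il1b, at -1.02, is in both the cytokine and the inflammasome lists, and Nlrp3 of the latter was at -0.43. None of the 40 lists passed the exact permutation of drug labels within LPS states, where the smallest adjusted p for the interaction was 0.3. Of the 119 genes higher in the average LPS effect, 91 had a smaller LPS effect with the drug. A narrower signal range on the telmisartan+LPS arrays would shrink all differences. Quantile normalization over all arrays takes out such a shrinkage. The SD over all features was 2.32, 2.35 and 2.33 on these arrays and 2.34, 2.33 and 2.34 on the LPS arrays. The slope over genes outside the LPS-changed set was 0.994, and 0.997 for the reverse regression. The range was thus about equal in the values used here, but the normalization sets this whatever the drug does. The slope and the SDs therefore cannot test this explanation, and they say nothing of the arrays before normalization. A single array is argued against, since the median interaction of -0.157 stayed between -0.18 and -0.118 when each array was left out. Chance in how the arrays fell into groups stays open (exact permutation, p = 0.115), and so does a damping of the LPS response by the drug. The interaction is the test of such a damping, and limma called 0 genes in it.

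Ribosomal protein genes had a mean interaction of 0.193, with 19 of 22 positive (camera in limma, adjusted p = 0.000374, and adjusted p = 0.354 with an estimated correlation), and oxidative phosphorylation genes one of 0.142, with 23 of 26 positive (camera in limma, adjusted p = 0.000479, and adjusted p = 0.51 with an estimated correlation). Both lists are bright, and a shift of all genes of that brightness could move them. Among 10000 random lists of the same size and brightness, oxidative phosphorylation lay at percentile 99.95 and ribosomal proteins at 100, which argues against that source. Recovery of small RNAs that differs between arrays cannot be told apart from an effect on these lists, because the within-group correlation of their array means with those of small nucleolar RNAs was 0.475 over 12 arrays in groups of 3 (exact permutation within groups, p = 0.38). No biological explanation beyond the treatment groups was tested.

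Features outside the gene table, with several symbol entries or none, held signals that the gene comparisons do not use. Of 17824 such features, 9 rose in LPS minus DMSO, the strongest by 2.27 (SE 0.14, limma with Benjamini-Hochberg adjustment, adjusted p = 0.000154), and 2 pairs among the 9 carried equal values. In telmisartan minus DMSO 1 rose, in telmisartan+LPS minus telmisartan 11 were called, 5 higher and 6 lower, and in the average telmisartan effect 1 rose.

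Counts of called genes were repeated over other splits of the arrays. For LPS minus DMSO, 1 of the 10 splits gave as many genes, the real one with 95, and the highest other gave 0. For telmisartan+LPS minus telmisartan it was likewise 1 of 10, with 58 in the real split and 0 in the highest other. A real count of 0 is reached by every split, so for telmisartan minus DMSO (10 of 10, highest other 0) and telmisartan+LPS minus LPS (10 of 10, highest other 5) the splits say nothing of chance. In these 4 comparisons 10 splits are too few for a share under 0.05. For the average telmisartan effect 14 of 100 splits drawn from 200 gave at least the real count of 1, with 3 in the highest other, so chance is not excluded. For the interaction the real count was 0, which all 100 drawn splits reach by construction, with 3 in the highest other, so these splits say nothing of chance either.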

How the results depend on the processing

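The genes chosen by the average LPS effect and the lists without LPS-called genes were alternatives chosen after seeing the data, and the others were fixed before the data were examined. The cause of each change below was not tested, except that a fold minimum lowers a count by construction. The precision of each value is limited by 3 arrays per group, and dim genes lie close to background.

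With a 1.5-fold minimum, genes past the threshold went from 95 to 62 in LPS minus DMSO and from 58 to 35 in telmisartan+LPS minus telmisartan, and a fit on the groups of that comparison alone also gave 35. With dim genes left out the counts were 126 for telmisartan+LPS minus telmisartan and 4 for the average telmisartan effect. Trend and robust options gave 164 for telmisartan+LPS minus telmisartan, 14 for telmisartan+LPS minus LPS, 1 for the interaction and 12 for the average effect. Every feature in place of 1 per gene gave 1 for telmisartan minus DMSO and moved the correlation of LPS effects from 0.34 to 0.227, and the genes chosen by the average LPS effect gave 0.958. The term for sets of 4 running numbers gave 0 for the average effect and changed no other count by over 1.5 times. The running numbers give no evidence of pairing, since arrays of the same set had correlations of their deviations between -0.047 and 0.081, and arrays of other sets between -0.073 and 0.073.

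Leaving out 1 array at a time gave 66 to 105 genes for LPS minus DMSO and 0 for telmisartan minus DMSO. Telmisartan+LPS minus LPS gave 0 to 5, with 5 without LPS replicate 3, all small nucleolar RNA genes higher with the drug, and 1 each without DMSO replicate 3 (lower) and telmisartan replicate 1 (H4c14, higher). Telmisartan+LPS minus telmisartan gave 31 to 66, with 31 without telmisartan replicate 3. The interaction gave 0 to 3, with 3 without LPS replicate 3, all small nucleolar RNA genes. The average effect gave 0 to 1, with H4c14 without telmisartan replicate 1 or 2, a small nucleolar RNA gene without LPS replicate 3, and 0 without any of DMSO replicates 1 to 3, LPS replicates 1 and 2, telmisartan replicate 3 and telmisartan+LPS replicates 1 to 3. LPS-changed genes moved back numbered 0 to 5, with 5 without LPS replicate 3, the small nucleolar RNA genes named above, lower after LPS and higher with the drug, and 1 without DMSO replicate 3, which had risen. The median drug change of LPS-raised genes stayed between -0.305 and -0.222.

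With an estimated correlation, lists past camera went from 12 to 7 for LPS minus DMSO, 3 to 0 for telmisartan minus DMSO, 12 to 3 for telmisartan+LPS minus LPS, 11 to 5 for telmisartan+LPS minus telmisartan, 6 to 0 for the interaction and 9 to 2 for the average effect. Without the genes called in LPS minus DMSO the counts were 4, 4, 1, 6, 2 and 4 in that order. Leave-one-out counts ran from 10 to 13 for LPS minus DMSO, 2 to 5 for telmisartan minus DMSO (5 without DMSO replicate 1), 6 to 12 for telmisartan+LPS minus LPS (6 without LPS replicate 2 and 7 without telmisartan+LPS replicate 2 or 3), 10 to 12 for telmisartan+LPS minus telmisartan, 4 to 9 for the interaction and 5 to 10 for the average effect (5 without telmisartan+LPS replicate 3).

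Over 114 named gene values, 2170 of 2371 values under an alternative kept direction and side of the threshold, 180 lost it, 12 gained it and 9 changed sign, all 9 on genes that passed no threshold. Agtr1b in telmisartan minus DMSO was at 0.0033 with centred arrays and at 0.014 with array weights. It was at -0.058 without DMSO replicate 3 and at 0.057 without telmisartan replicate 3. Agtr1a was at -0.10 without telmisartan replicate 1 and at 0.058 without telmisartan replicate 2, where Pparg was at -0.052, and Pparg was at 0.11 without DMSO replicate 3. Tlr4 in LPS minus DMSO was at -0.0067 without LPS replicate 1 and at 0.20 without DMSO replicate 3.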

Other observations

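The gene classes in this part, histones and small nucleolar RNAs, were chosen only after the results were seen, as were all tests on them.

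Of 73 small nucleolar RNA genes, which guide chemical modification of ribosomal RNA, 56 were lower in LPS minus DMSO with a median of -0.257, 0 over all genes tested and 24 lower and 2 higher adjusted over the list alone. In telmisartan+LPS minus LPS 62 were higher with a median of 0.35, 0 over all genes tested and 31 adjusted over the list alone, and in the interaction 65 were positive with a median of 0.503, 0 over all genes tested and 28 adjusted over the list alone. In telmisartan+LPS minus telmisartan 60 were higher with a median of 0.193, 1 over all genes tested and 12 adjusted over the list alone, and in telmisartan minus DMSO 63 were lower with a median of -0.133, 0 over all genes tested and 0 adjusted over the list alone. Counts depended on single arrays. Over all genes tested, without LPS replicate 3, 15 were lower in LPS minus DMSO, 5 higher in telmisartan+LPS minus LPS, 3 higher in telmisartan+LPS minus telmisartan, 3 positive in the interaction and 1 higher in the average telmisartan effect. In LPS minus DMSO 2 were lower without LPS replicate 1, 1 each without telmisartan replicate 1 and telmisartan+LPS replicate 3, 3 lower and 2 higher without telmisartan+LPS replicate 1, and 1 higher without telmisartan+LPS replicate 2. The counts adjusted over the list alone moved too. In LPS minus DMSO the lower genes numbered 14, 6 and 9 without DMSO replicates 1, 2 and 3, 6 without LPS replicate 1 and 4 without LPS replicate 2. In telmisartan+LPS minus LPS the count was 13 without LPS replicate 2, 19 without telmisartan+LPS replicate 2 and 12 without telmisartan+LPS replicate 3, and in the interaction it was 15 without DMSO replicate 2, 13 without LPS replicate 2 and 18 without telmisartan+LPS replicate 3. In telmisartan+LPS minus telmisartan it was 7 without telmisartan replicate 2, 22 without telmisartan+LPS replicate 1 and 6 without telmisartan+LPS replicate 3, and the 1 gene over all genes tested was lost when telmisartan replicate 1, 2 or 3 was left out. Their mean signal was 8.598 ± 0.085 (SD, n = 3) in DMSO, 8.283 ± 0.21 (SD, n = 3) in LPS, 8.449 ± 0.033 (SD, n = 3) in telmisartan and 8.651 ± 0.19 (SD, n = 3) in telmisartan+LPS. Single arrays overlapped, with LPS replicate 3 at 8.519, above DMSO replicate 1 at 8.503, and LPS replicates 1 and 2 at 8.2 and 8.13. Telmisartan+LPS replicate 1, at 8.448, did not exceed the telmisartan mean, and replicate 3 of that group was at 8.822. The same LPS arrays enter LPS minus DMSO, telmisartan+LPS minus LPS and the interaction, so these shifts are not separate evidence. Recovery of small RNAs that differs between arrays was not tested for these genes themselves and cannot be told apart from a treatment effect.

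Array medians lay between 4.08 and 4.13, and for markers of other cell types the mean signal was 3.82 for 8 astrocyte markers, 3.8 for 8 neuron markers, 3.79 for 7 fibroblast markers and 4.89 for 7 endothelial markers. Only oligodendrocyte markers, at a mean signal of 4.26, passed camera in any comparison, higher by a mean of 0.0852 in the average telmisartan effect with 0 genes past the threshold over all genes tested and 0 adjusted over the list alone (camera in limma, adjusted p = 0.046, and adjusted p = 0.197 with an estimated correlation). That call was kept only without LPS replicate 2, telmisartan replicate 2 or telmisartan+LPS replicate 2, and the adjusted p of camera in limma reached 0.13 without LPS replicate 1.

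Histone genes were higher with the drug under LPS, 25 of 29 with a median of 0.207, 0 over all genes tested and 6 adjusted over the list alone, and in the average telmisartan effect 24 of 29 were higher, 1 over all genes tested (H4c14, a call kept only without telmisartan replicate 1 or 2 when an array was left out) and 7 adjusted over the list alone. In telmisartan minus DMSO their median was 0.02, with 18 of 29 higher, 0 over all genes tested and 2 adjusted over the list alone. It was 0.0433, 0.0133 and 0.00667 without DMSO replicates 1, 2 and 3, and 0.0633, -0.0167 and 0.08 without telmisartan replicates 1, 2 and 3. Their mean signal was 6.333 in DMSO and 6.411 in telmisartan. A larger share of cells in S phase could raise them. The S phase list had a mean of -0.016 in telmisartan+LPS minus LPS, at most 0.00851 when an array was left out. This argues against an increase that would raise the S phase list about as much as the histone genes. A smaller increase is not excluded, because how far the S phase list moves for a given rise of histone genes was not measured. Recovery of small RNAs cannot be told apart from an effect of the drug, because the within-group correlation of histone and small nucleolar RNA array means was -0.105 (exact permutation within groups, p = 0.855).

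On DMSO replicate 3, 1 feature with no listed gene had a log2 signal of 13.98, where the other arrays lay between 1.78 and 3.54.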
